A study of Mus musculus with 16 samples.

How the data were processed

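RNA from the gastrocnemius muscle of 16 mice was measured with 1 array per mouse. Per the labels' protocols, total RNA was extracted with RNeasy columns and 250 ng of it was turned into biotin-labelled cRNA by Affymetrix's standard procedure. The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, normalization between arrays and summary of probes) in the oligo package, per the submitters' processing notes, which give no versions. The log base was read from the values, which lie between 0.33 and 13.84. The array design, the genome build behind it and the scan dates are not given in the sources used here, so a scan batch could not be examined. RMA sets the arrays to a common distribution, so a change of all transcripts at once would not be seen, and dim probe sets show compressed fold changes. For arrays the number of mice limits the precision.

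Mice were grouped by their labels, 8 Cre-negative controls and 8 with Cre and the FoxO1, FoxO3 and FoxO4 deletion, each called a separate biological replicate. All 16 columns were matched to a mouse. Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none. Only probe sets with 1 symbol were named. A probe set was kept if it lay above the array median in at least 8 of the 16 mice, and of several for a gene the brightest on average was used, which left 13601 genes. Chromosomes and gene order come from the RefSeq annotation of GRCm38.p6, which placed 13540 of the genes tested. No coordinates are given, since the array's build is unknown here. No mouse was left out of the tests, and no 2 arrays were duplicates (highest correlation 0.982).

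The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term, two-sided tests and Benjamini-Hochberg adjustment over the genes tested. Adjusted p-values of single genes in the text are limma's, and a gene passed if its value was under 0.05. Single values with 8 mice per group were tested by exact permutation over all 12870 splits of the mice, the smallest possible p being 1.55e-04. The 34 gene lists, 12 of them markers of cell types, were fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, with camera on ranks, with fry (which asks whether a list's genes move, on balance, in 1 direction, or in its other form in either direction) and with an exact permutation test of the list mean per mouse, each adjusted over the 34 lists. List members without a single-symbol probe set or under the filter were not tested. Intervals are 95% confidence intervals.

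The genes named in the text were set by a rule fixed together with the lists: the FoxO genes, the 12 largest rises and 12 largest falls among genes past the threshold, leaving out predicted genes and Riken clones, and up to 2 members with the smallest p in each direction of each list described. Genes outside the rule were chosen after their values were seen: Acot11 and its neighbours, Emcn, Plk2, Tango2, Itgam, Hif1a, Vegfc, Prox1, Pdpn, Ptprc, Fmod, Fabp4, Elovl5, Acly, Gclc, Alb and those in the closing section. A list of liver transcripts and a list of tendon transcripts were added after the data were seen. A gene whose controls all lay under their array median was given its fold as a lower bound, counted from the mean of those medians.

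The procedure was tested on simulated values with the groups' real spread, 8 against 8 mice and 13601 genes, of which 200 were changed. Of 100 genes changed by 0.5 log2 units 76 were recovered, and of 100 changed by 1 log2 unit 97 were, with 4 false calls. A list shifted by 0.3 was called by camera, and 0 of 32 lists that shared no gene with it were. The simulation was built from the spread of genes and not from the correlation between them. In the real lists the estimated correlation ran from -0.019 (denervation response) to 0.823 (Schwann cells), against the preset 0.01. In other splits of the real mice camera called a median of 9 lists. The simulation therefore cannot show how often camera calls unshifted lists in the real data.

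Alternatives set beforehand were no filter and a filter at the 75th percentile, centring of arrays, quantile normalization, the mean of a gene's probe sets, all probe sets tested separately, a trended and robust variance, array weights, Welch's test per gene, the replicate number as a block, the leading component of the residuals and the slow fibre list as covariates, an adjusted p under 0.10, other set tests and leaving out each mouse. The 19 genes past the threshold that were named after their values were seen and are given as changed were put through the same settings. Added after the data were seen were the liver list as a covariate and leaving out the mice with high Alb. Figures were drawn with matplotlib.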

Results

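Whole gastrocnemius muscle, the large fast-twitch muscle of the calf, was profiled with 1 expression array per mouse in 16 male FVB/n mice killed at 16 weeks of age. All mice carried Foxo1, Foxo3 and Foxo4 alleles flanked by loxP sites. Their food in the last 8 weeks was a high-fat diet, with 58% fat, 16.4% protein and 25.5% carbohydrate. The deletion group (n = 8) also carried Mx1-Cre, a recombinase gene under an interferon-responsive promoter. The control group (n = 8) was made up of littermates without Cre. Injections of polyinosine:cytidine, an RNA mimic that sets off interferon, were given 3 times at 4 to 5 weeks of age to switch Cre on. Per the labels the deletion was directed at the endothelium, the cell layer that lines blood vessels. The comparison asks how muscle gene expression under high-fat feeding differed when the FoxO transcription factors had been deleted. Cre was carried by every deletion mouse and by no control. Effects of Cre itself, or of DNA inherited with it, therefore cannot be told apart from those of the deletion for any gene. Array medians lay between 4.43 and 4.61 on the log2 scale, and correlations between arrays ran from 0.958 to 0.982. The first principal component of the genes tested held 22.9% of the variance, and its scores differed between the groups (exact two-sided permutation p = 0.0017, n = 8 and 8). Deletion mouse 8, at -14.7, lay among the controls on this component, which ran from -15.7 to -0.188.

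The transcripts of the targeted genes did not fall past the threshold in whole muscle. Foxo1, on chromosome 3, read 7.29 ± 0.06 log2 units in the controls and 7.36 ± 0.36 in the deletion mice (SD, n = 8 each), a difference of 0.07 (SE 0.12, limma adjusted p = 0.804). Foxo3, on chromosome 10, was nominally higher with deletion, at 5.88 ± 0.40 against 5.38 ± 0.16, with 6 of 8 deletion mice above every control. The difference of 0.50 (SE 0.14) missed the threshold over all genes (limma adjusted p = 0.0762; unadjusted exact permutation p = 0.0017). Foxo4, on the X chromosome, read 7.18 ± 0.26 in the deletion mice against 7.42 ± 0.15, a difference of -0.24 (SE 0.10, limma adjusted p = 0.236, exact permutation p = 0.0423). Foxo6, a family member that was not targeted, differed by -0.19 (SE 0.08, limma adjusted p = 0.215). By mouse from 1 to 8, Foxo1 read 7.38, 7.31, 7.25, 7.23, 7.34, 7.28, 7.22 and 7.30 in the controls, and 7.25, 7.30, 7.05, 8.23, 7.41, 7.25, 7.22 and 7.18 in the deletion mice. Foxo3 read 5.19, 5.50, 5.32, 5.45, 5.19, 5.34, 5.40 and 5.66 in the controls, and 5.73, 5.80, 5.82, 6.66, 5.83, 6.23, 5.51 and 5.42 in the deletion mice. Foxo4 read 7.39, 7.28, 7.37, 7.51, 7.73, 7.32, 7.26 and 7.45 in the controls, and 6.77, 7.48, 6.99, 7.16, 7.46, 6.95, 7.35 and 7.26 in the deletion mice. The other Foxo1 probe set above the filter differed by -0.03 (SE 0.09). Whether any of these probe sets lie in the deleted exons was not analysed here, and a probe outside them checks nothing about the deletion. Whole muscle also holds FoxO transcripts of cells outside the endothelium, at which the deletion was not directed per the labels. Whether Mx1-Cre also acted in those cells was not tested. These values therefore cannot show how far the genes were deleted. Without deletion mouse 4 the Foxo1 difference turned to -0.05, and without deletion mouse 8 the Foxo3 difference of 0.56 passed the threshold.

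**Figure D1:**
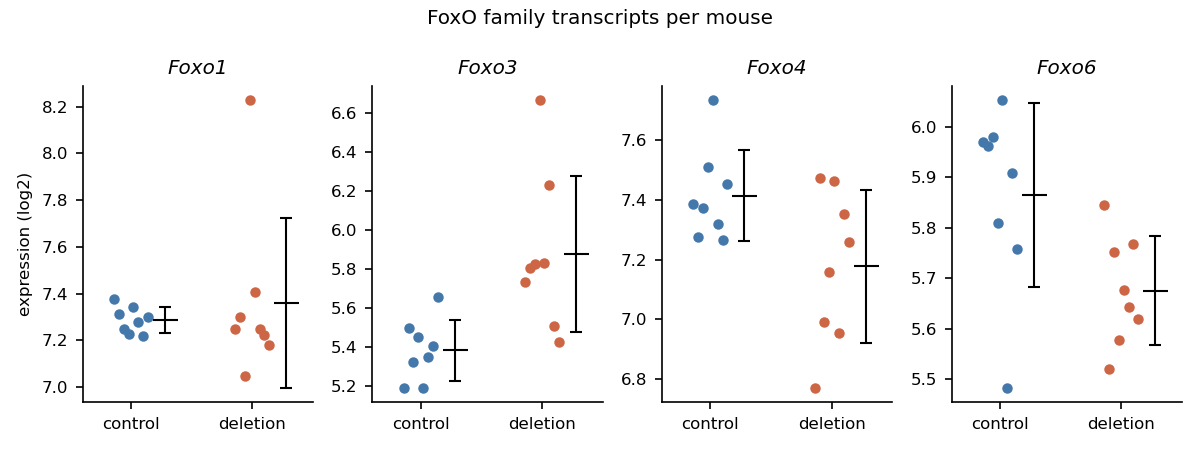
Expression of Foxo1, Foxo3, Foxo4 and Foxo6 on the log2 scale (vertical axes, which do not start at 0 and differ between panels) in the 8 control and 8 deletion mice, with 1 point per mouse and the mean ± SD in black beside them. Deletion mouse 4 stands at 8.23 for Foxo1, above the other 7 deletion mice, and 6 of 8 deletion mice lie above every control for Foxo3.

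Hsd3b6, a hydroxysteroid dehydrogenase of steroid synthesis, rose at least 13.4-fold with deletion (limma adjusted p = 4.73e-06), and every deletion mouse lay above every control. Apol11b, an apolipoprotein L gene, rose by 2.87 (SE 0.62), and Enpp6, a choline phosphodiesterase, rose by 1.72 (SE 0.18). Apln, which encodes the vessel growth peptide apelin, rose by 1.19 (SE 0.19), and Fabp5, a fatty acid binding protein, rose by 1.11 (SE 0.13). The genes that fell included Prkaa2, the alpha 2 catalytic subunit of AMP-activated protein kinase, at -0.93 (SE 0.08, limma adjusted p = 1.40e-06), and Usp24, a deubiquitinase, at -1.03 (SE 0.06, limma adjusted p = 3.50e-08). Of 13601 genes tested, 249 changed at a limma adjusted p under 0.05, 208 higher and 41 lower. An unadjusted p under 0.05 was found for 2352 genes, where chance gives 680. The rise reached 2-fold in 13 genes and the fall reached 2-fold in 2. Among the 249, the 8 deletion mice and the 8 controls did not overlap for 33 of the higher and 12 of the lower genes. Chance gives this arrangement to 0.0155% of unselected genes. That share does not apply to genes already chosen for their difference, and the count over all genes tested was not made.

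Hsd3b6 (probe set 17408345, chromosome 3) measured 3.05 ± 0.65 in the controls and 8.30 ± 1.38 in the deletion mice. All 8 controls were below their array median, so the fitted difference of 5.25 (SE 0.47) has no exact meaning. The lower bound was counted from the mean control array median of 4.55, which lies 3.75 log2 units under the deletion mean. Apol11b measured 5.16 ± 0.69 against 8.03 ± 1.90, with 7 of 8 deletion mice above every control (limma adjusted p = 0.0244). Both genes, like Apol7e, have close relatives in gene families, and how far probes are shared with these was not analysed here. Other rises were those of Trim59 (1.79, SE 0.39), Lrat, the retinol esterifying enzyme (1.58, SE 0.27), and S100a8, a calcium-binding protein of neutrophils (1.28, SE 0.27). Most controls were also below their array median for Lrat (7 of 8), S100a8 (6 of 8) and Apln (6 of 8), whose deletion means lay 1.10, 1.17 and 0.99 above the control array median. Further rises were those of Trp53i11 (1.24, SE 0.21), Vsig4, a complement receptor of resident macrophages (1.17, SE 0.21), F13a1, the coagulation factor XIII A chain (1.10, SE 0.24), and Prcp, a carboxypeptidase (1.09, SE 0.16). On the falling side Kera, the corneal and tendon proteoglycan keratocan, changed most among the named genes at -1.19 (SE 0.24). After Usp24 and Prkaa2 came Cdr2 (-0.88, SE 0.17), Mettl11b (-0.76, SE 0.18), Ttc4 (-0.64, SE 0.07), Myorg (-0.62, SE 0.13) and the microRNA gene Mir466h (-0.62, SE 0.11). Smaller falls were those of Apol7e (-0.61, SE 0.14), Zfp773 (-0.57, SE 0.11), Plpp3, a lipid phosphatase (-0.55, SE 0.09), and Angpt1, the vessel-stabilising ligand angiopoietin 1 (-0.50, SE 0.11). Their limma adjusted p-values ran up to 0.0382, for Mettl11b. Centring each array on the median of the genes tested gave 126 higher and 67 lower genes, so that the higher share moved from 83.5% to 65.3%. A further quantile normalization gave 142 and 55, a higher share of 72.1%.

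The number of changed genes depended on single mice. It was 160, 154, 129, 131, 143 and 135 without controls 1, 2, 3, 5, 6 and 7. It was 134, 127, 158, 107 and 162 without deletion mice 1, 2, 5, 6 and 7, and 680 without deletion mouse 8. Of the 33 genes past the threshold that the rule for named genes chose, 26 stayed past it whichever mouse was left out. Over the 16 such fits the call was lost for Mettl11b and Angpt1 in 9 each, Apol7e in 8, F13a1 in 5, Trim59 and Rpl3 in 3 each and Apol11b in 1, with adjusted p-values from limma of at most 0.0853.

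**Figure D2:**
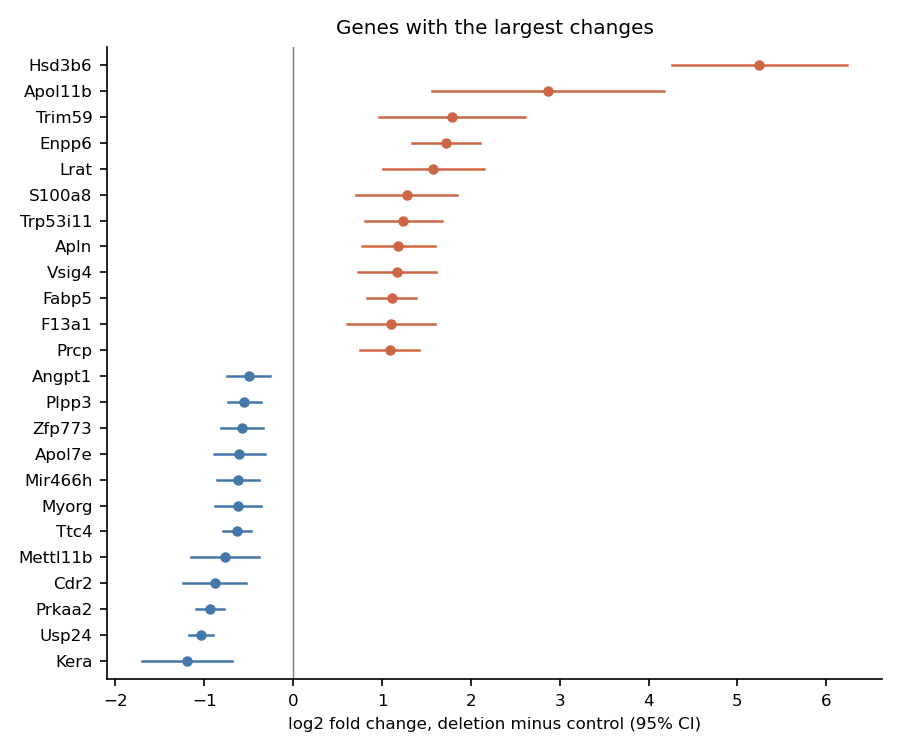
Log2 fold change, deletion minus control (horizontal axis), of the 12 named genes with the largest rises and the 12 with the largest falls among those past the threshold, with bars for the 95% confidence interval from 8 mice per group. Hsd3b6 is drawn at its fitted 5.25, but all 8 controls were under their array median and only a rise of at least 3.75 is measured; the falls run from -1.19 for Kera to -0.50 for Angpt1.

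Prkaa2, Plpp3, Usp24, Ttc4 and Acot11, which all fell, lie within 6 consecutive tested genes of chromosome 4 in the gene order of the GRCm38.p6 annotation. Acot11, an acyl-CoA thioesterase, fell by 0.50 (SE 0.10, limma adjusted p = 0.0146). It lies outside the rule for named genes and was chosen after its values were seen, as was the region. Every deletion mouse lay below every control for Prkaa2 (9.86 ± 0.14 against 10.79 ± 0.15), Usp24 (8.45 ± 0.14 against 9.48 ± 0.08), Ttc4 (6.66 ± 0.12 against 7.29 ± 0.16) and Plpp3 (7.89 ± 0.20 against 8.44 ± 0.16). Of the 6 consecutive tested genes from Prkaa2 to Acot11, only Ttc22 did not pass, at 0.08 (limma adjusted p = 0.716). The nearest tested neighbours outside them were Gm12718 at 0.16 and Oma1 at -0.14 on the Prkaa2 side and Ssbp3 at -0.17 on the Acot11 side, none of which passed the threshold.

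**Figure D3:**
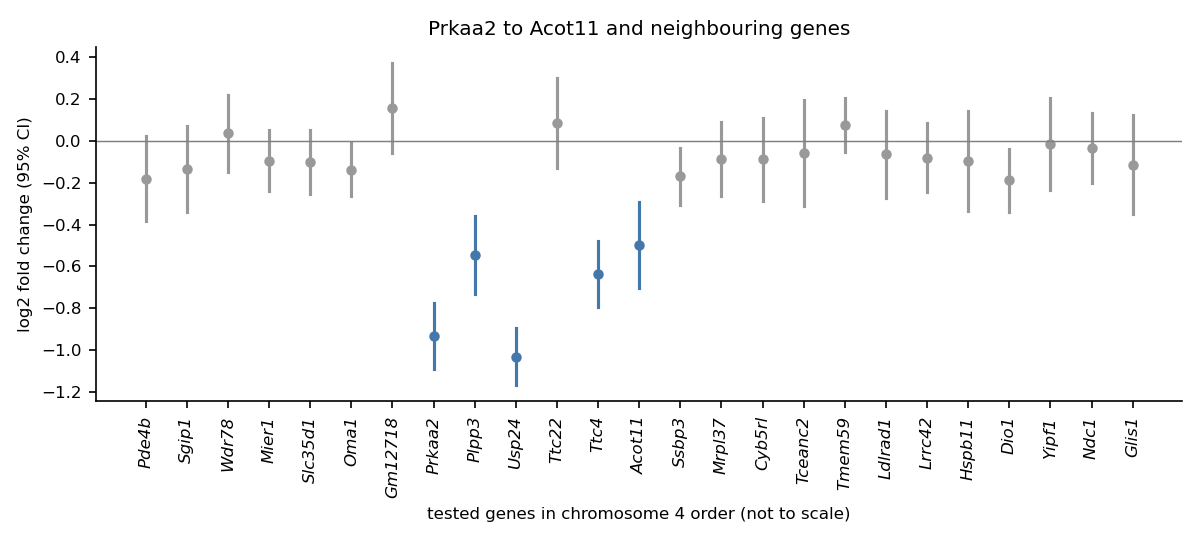
Log2 fold change, deletion minus control (vertical axis), with 95% confidence intervals for tested genes in their order along chromosome 4 (horizontal axis, not to scale), where blue marks genes past the threshold. Prkaa2 at -0.93, Plpp3 at -0.55, Usp24 at -1.03, Ttc4 at -0.64 and Acot11 at -0.50 lie below the genes on either side.

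The list of endothelial cell markers was higher in the deletion mice, with 14 of 35 members past the threshold and 21 not. The mean of the 35 measured members was 7.17 ± 0.20 against 6.80 ± 0.11 log2 units (SD, n = 8 each), a difference of 0.37 (95% interval 0.20 to 0.55), and 6 of 8 deletion mice lay above every control (exact permutation p adjusted over 34 lists = 0.0185). The adjusted p from camera was 3.33e-17 with a preset correlation between genes, adjusted p = 0.333 with an estimated correlation, and fry gave an adjusted p of 0.0102. Without the 6 mice with high Alb described at the end, the difference was 0.24 (exact permutation p = 0.0429 before adjustment). With 6 against 4 mice an exact p cannot go below 0.00476, or 0.162 for a single list after adjustment over 34, so a list could hardly pass there. All 14 members past the threshold over all genes were higher, as were 19 when adjusted over the list alone. Erg, an endothelial transcription factor, rose by 0.52 (SE 0.08) in 8 of 8 mice beyond the control range, and Ptprb, the endothelial receptor phosphatase VE-PTP, rose by 0.73 (SE 0.12). Sox18 and Robo4 were among the 21 that did not pass, at -0.08 (SE 0.15) and -0.03 (SE 0.09). The lymphatic endothelial list also shifted, by 0.34 (0.15 to 0.54, exact permutation p adjusted = 0.0370), with 2 of 6 members higher over all genes and 3 when adjusted over the list alone, and adjusted p = 0.333 with an estimated correlation. Lyve1, the hyaluronan receptor of lymphatic vessels that some tissue macrophages also carry, rose by 0.72 (SE 0.11), Flt4, the receptor for VEGF-C, rose by 0.39 (SE 0.08), and Mmrn1 differed by -0.01 (SE 0.12). The lymphatic markers Prox1 and Pdpn did not pass, at 0.17 (SE 0.17) and 0.14 (SE 0.12). Without the mice with high Alb the lymphatic list differed by 0.30 (camera adjusted p = 0.0182, exact permutation p = 0.0667 before adjustment).

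**Figure D4:**
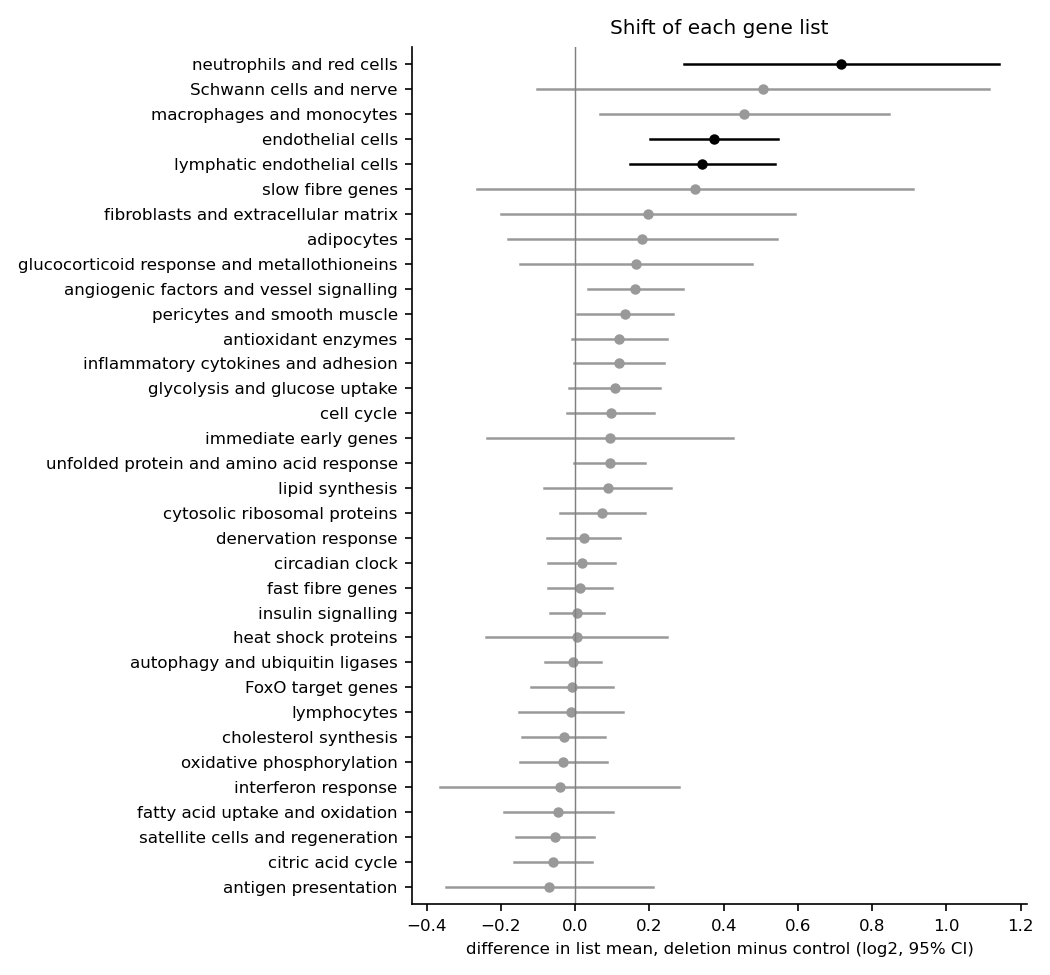
Difference between deletion and control mice in the mean log2 value of each of the 34 gene lists (horizontal axis), with 95% confidence intervals from 8 mice per group, in black where the exact permutation test passed after adjustment. The lists in black are neutrophils and red cells at 0.72, endothelial cells at 0.37 and lymphatic endothelial cells at 0.34.

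Among blood and immune cell markers, the list of neutrophil and red cell genes passed the exact test and the macrophage and lymphocyte lists did not. The neutrophil and red cell list shifted by 0.72 (95% interval 0.29 to 1.14), with 6 of 8 deletion mice above every control (exact permutation p adjusted = 0.0185, adjusted p = 0.342 with an estimated correlation). Without the mice with high Alb the shift was 0.52 (exact permutation p = 0.0238 before adjustment). S100a8 was the 1 member of 6 past the threshold over all genes, and 5 were higher when adjusted over the list alone, among them Csf3r, the receptor for the neutrophil growth factor G-CSF, at 0.32 (SE 0.09). The macrophage and monocyte list differed by 0.45 (0.07 to 0.84), which passed with camera (adjusted p = 7.64e-09) but not with an exact permutation of the list mean (adjusted p = 0.137). It had an adjusted p = 0.680 with an estimated correlation and 0.122 with fry. In that list 4 of 21 members rose over all genes and 13 when adjusted over the list alone. Mertk, a receptor for dying cells, rose by 0.42 (SE 0.08), C1qa of the complement cascade by 0.56 (SE 0.11), Itgam by 0.69 (SE 0.17, a call lost in 11 of 16 fits without 1 mouse) and F13a1 as above, while the scavenger receptor Cd163 differed by -0.11 (SE 0.15). The lymphocyte list did not shift (-0.01, -0.15 to 0.13), although Ptprc, which encodes the antigen CD45 of all white cells, rose by 0.73 (SE 0.17, limma adjusted p = 0.0397), a call lost in 13 of 16 fits without 1 mouse.

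Most of the genes of vessel growth that passed the threshold were higher. Of 47 measured angiogenic factors and vessel signalling genes, 7 rose and 1 fell over all genes, and 9 rose and 2 fell when adjusted over the list alone. Besides Apln, the neuropilin Nrp2 rose by 0.64 (SE 0.12), Hif1a by 0.42 (SE 0.08) and Vegfc by 0.50 (SE 0.12, a call lost in 11 of 16 fits without 1 mouse). Angpt1 fell, a call lost in 9 of 16 such fits, and the chemokine receptor Cxcr4 differed by -0.35 (SE 0.11) without passing. The list mean differed by 0.16 (0.03 to 0.29), past the threshold with camera (adjusted p = 9.60e-04) but not with the exact permutation test (adjusted p = 0.137), and adjusted p = 0.718 with an estimated correlation. Without the mice with high Alb it was 0.077 and camera's call was lost (adjusted p = 0.0917). The inflammatory cytokine and adhesion list differed by 0.12 (-0.00 to 0.24), with camera adjusted p = 0.0340 and adjusted p = 0.718 with an estimated correlation. Camera's call was lost without the mice with high Alb (0.10, adjusted p = 0.0735), and kept in 11 of 16 fits without 1 mouse. In it Vcam1, a leukocyte adhesion molecule, rose by 0.79 (SE 0.12) as 1 of 22 members over all genes and 1 of 2 when adjusted over the list alone, Nfkbia differed by 0.30 (SE 0.09), Ccl5 by -0.35 (SE 0.15) and Socs3 by -0.07 (SE 0.09).

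The lists that follow passed with camera at its preset correlation and with camera on ranks, but not with fry in 1 direction or with the exact permutation test. Pericyte and smooth muscle markers differed by 0.13 (0.00 to 0.26), with 0 of 14 past the threshold over all genes and 2 when adjusted over the list alone, camera adjusted p = 0.0232 and adjusted p = 0.718 with an estimated correlation. Their examples were Pdgfrb at 0.27 (SE 0.08), Mcam at 0.32 (SE 0.10), Abcc9 at -0.11 (SE 0.06) and Lmod1 at -0.02 (SE 0.07). Without the mice with high Alb the shift was 0.12 and camera's call was lost (adjusted p = 0.0845). Schwann cell and nerve markers differed by 0.51 (-0.10 to 1.11), with 0 of 10 past the threshold over all genes or the list alone, and Pmp22 at 1.03 (SE 0.33) and Mal at 1.12 (SE 0.48); camera gave an adjusted p of 0.00562, and adjusted p = 0.807 with an estimated correlation. In deletion mice 2, 4, 6 and 7 the Schwann cell list stood at 6.84, 7.03, 7.04 and 7.05, and in the other deletion mice between 5.59 and 6.13. Control 1 stood at 6.95 and the other controls between 5.59 and 5.88. The same p with an estimated correlation, 0.807, was found for the 3 lists that follow. Glycolysis and glucose uptake genes differed by 0.11 (-0.02 to 0.23, 0 of 22 past the threshold), with the glucose transporter Slc2a1 at 0.47 (SE 0.14), Pfkp at 0.27 (SE 0.11), Pfkm at -0.05 (SE 0.08) and Ldhb at -0.03 (SE 0.13). The shift was 0.026 without the mice with high Alb (camera adjusted p = 0.588), and camera kept its call in 9 of 16 fits without 1 mouse. Citric acid cycle genes differed by -0.06 (-0.17 to 0.05, 0 of 23 past the threshold), with Sucla2 at -0.21 (SE 0.08), Suclg2 at -0.20 (SE 0.08), Pcx at 0.12 (SE 0.10) and Pdk4 at 0.01 (SE 0.14). This shift was -0.15 without the mice with high Alb, with a camera adjusted p of 1.67e-05, an exact permutation p of 0.0238 before adjustment and adjusted p = 0.513 with an estimated correlation. Camera kept the call in 14 of 16 fits without 1 mouse. Cytosolic ribosomal protein genes differed by 0.07 (-0.04 to 0.19), with 1 of 28 past the threshold, Rpl3, at 0.63 (SE 0.14), and with Rpl32 at 0.19 (SE 0.08), Rps16 at -0.34 (SE 0.17) and Rps24 at -0.15 (SE 0.10), and camera kept its call in 11 of 16 fits without 1 mouse. In all, camera called 11 of 34 lists, 10 higher and 1 lower, camera on ranks called 16, fry for change in either direction called 9, while fry and the exact permutation test each called 3 and camera with an estimated correlation called 0. Without deletion mouse 6 camera called 6 lists.

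The 31 measured FoxO target genes did not shift as a group, with a difference of -0.01 (-0.12 to 0.10) and 0 members past limma's threshold over all genes or adjusted over the list alone. Of them 3 had an unadjusted p under 0.05, and the exact permutation p of the list mean was 0.862 before adjustment. Without the 6 mice with high Alb the FoxO list differed by -0.13, which passed with camera (adjusted p = 0.00189, against up to 0.932 over all settings), with an exact permutation p of 0.00952 before adjustment. There the adjusted p = 0.432 with an estimated correlation. Whole muscle was measured, while the deletion was directed at the endothelium per the labels. FoxO target transcripts of other cells, such as the fibres, could therefore hide a change in endothelial cells. The muscle ubiquitin ligase genes Trim63 and Fbxo31 differed by -0.29 (SE 0.11) and -0.24 (SE 0.10), and the cell death genes Bnip3 and Bcl2l11 by 0.32 (SE 0.12) and 0.20 (SE 0.11). Insulin signalling genes differed by 0.00 (-0.07 to 0.08), with 0 of 28 past the threshold, among them Ptpn1 at 0.23 (SE 0.08), Igf1 at 0.38 (SE 0.19), Ppp1r3a at -0.19 (SE 0.07) and Tbc1d1 at -0.42 (SE 0.15). Fatty acid uptake and oxidation genes differed by -0.05 (-0.19 to 0.10), with 0 of 34 past the threshold, among them Cpt1a at 0.35 (SE 0.15), Angptl4 at 0.24 (SE 0.24), Fabp3 at -0.23 (SE 0.08) and Cpt2 at -0.28 (SE 0.10). The fatty acid list missed the threshold with camera (adjusted p = 0.0637) and passed it in 14 of 35 other settings, always lower, among them ranks (adjusted p = 0.0376) and the fit without the mice with high Alb (-0.18, adjusted p = 9.34e-08, exact permutation p = 0.0238 before adjustment). In that fit the fatty acid list had an adjusted p = 0.513 with an estimated correlation. Interferon response genes differed by -0.04 (-0.36 to 0.28), with 0 of 30 past the threshold. The difference turned to 0.09 without control 7, and that of antigen presentation genes turned from -0.07 to 0.038. Interferon examples were Isg15 at 0.81 (SE 0.47), Xaf1 at 0.18 (SE 0.10), Cxcl10 at -0.16 (SE 0.08) and Gbp3 at -0.42 (SE 0.21). The Isg15 and Gbp3 differences lean on single mice. Isg15 read 8.75 in deletion mouse 4 and at most 6.60 in the other deletion mice. Gbp3 read 6.84 in control 7 and at most 5.75 in the other controls. The counts at an unadjusted p under 0.05 were 3 for insulin signalling, 3 for fatty acid genes and 0 for interferon genes. Oxidative phosphorylation (-0.03), slow fibre genes (0.32), fibroblasts and extracellular matrix (0.20) and the unfolded protein and amino acid response (0.09) missed the threshold with camera, fry and the exact test. On ranks they passed, with adjusted p-values of 0.0376 for the former 3 and 0.0329 for the last, and over 35 settings they passed in 14, 8, 11 and 10. Without the mice with high Alb camera called oxidative phosphorylation (-0.10, adjusted p = 6.90e-06), slow fibre genes (0.42, adjusted p = 0.0300) and fibroblasts (0.21, adjusted p = 0.0324). It did not call the unfolded protein list there (adjusted p = 0.352). With an estimated correlation the adjusted p-values of these lists in that fit ran from 0.734 to 0.736. No shift passed with camera on values or ranks, fry in 1 direction or the exact test for autophagy and ubiquitin ligases (-0.01), denervation response (0.02), fast fibre genes (0.01), adipocytes (0.18) or satellite cells and regeneration (-0.05). The same held for lipid synthesis (0.09), cholesterol synthesis (-0.03), antigen presentation, circadian clock (0.02), immediate early genes (0.09), glucocorticoid response and metallothioneins (0.16), heat shock proteins (0.00), antioxidant enzymes (0.12) and cell cycle (0.10). Without the mice with high Alb camera called autophagy (-0.081, adjusted p = 0.0411) and cholesterol synthesis (-0.089, adjusted p = 0.0470). With an estimated correlation their adjusted p-values there were 0.513 and 0.734. In that fit immediate early genes turned to -0.10 and the glucocorticoid list to -0.086. Over 35 settings adipocytes passed in 4, the glucocorticoid list in 2 and heat shock proteins in 1. Fry's test for change in either direction passed for satellite cells (adjusted p = 1.05e-05), lipid synthesis (0.00932) and antioxidant enzymes (0.0483). Single members of these lists passed over all genes and when adjusted over the list alone: Vcam1 of the satellite cell list at 0.79, Fmod, a collagen-binding proteoglycan, at -0.49, Fabp4 of adipocytes at 0.49, Elovl5 and Acly of lipid synthesis at 0.43 and 0.35, and Gclc of glutathione synthesis at 0.40. Without 1 mouse the call was lost for Acly in 10 of 16 fits and for Gclc in 4.

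Transcripts of liver and plasma proteins were high in some mice of both groups. The mean of 20 such genes, a list drawn up after the data were seen, ran from 4.89 to 7.47 in the controls and from 4.80 to 7.78 in the deletion mice, and Alb, which encodes albumin, ran from 4.23 to 11.68 over the 16 mice. The group difference of the liver list mean was 0.47 (95% interval -0.76 to 1.70, exact permutation p = 0.407). With limma 0 of the 20 genes passed the threshold, with 1 at an unadjusted p under 0.05. Without the 6 mice whose Alb value lay more than 4 log2 units above the lowest, a choice also made after the data were seen, 4 deletion mice and 6 controls remained and 7 genes passed. Hsd3b6, Enpp6, Emcn and Plk2 were higher, and Usp24, Prkaa2 and Tango2 were lower, of which Tango2 was not among the 249 (-0.22, limma adjusted p = 0.430 over all mice). All 249 genes kept their direction without those mice, with a median of 0.889 times the log2 fold change. Removing as many mice of each group at random gave a median of 19.5 genes over 100 draws, with 7 or fewer in 25.

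**Figure D5:**
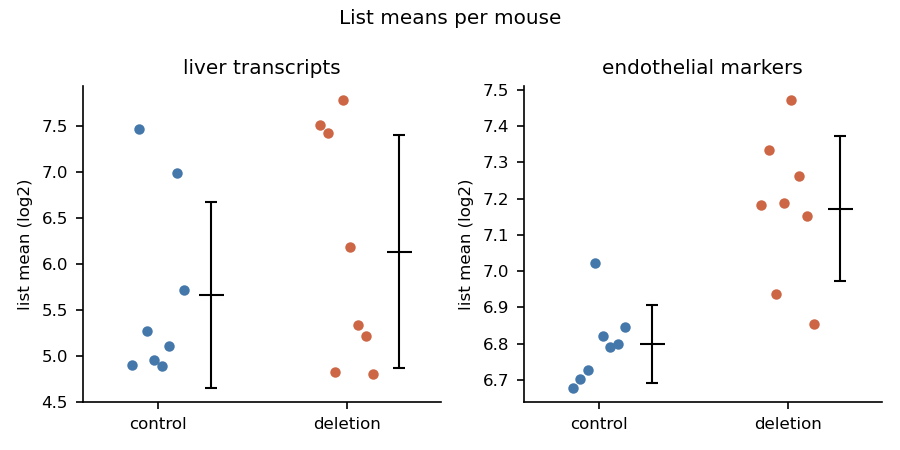
Mean log2 value (vertical axes, which do not start at 0) of the 20 liver transcripts and of the 35 endothelial markers in each control and deletion mouse, with 1 point per mouse and the mean ± SD in black. The liver list spreads from 4.80 to 7.78 over both groups, while the endothelial list has 6 of 8 deletion mice above every control.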

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

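The tests of gene order, of fibre RNA and of liver RNA were chosen after their results were seen, and the chromosome 4 and liver patterns were noticed in these data before they were tested.

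The fall of Prkaa2, Plpp3, Usp24, Ttc4 and Acot11 concerns a single stretch of chromosome 4, whose mean over these genes fell by 0.73 (95% interval -0.81 to -0.65). When the 41 fallen genes were shuffled over all gene positions, 0 of 10000 shuffles put 5 into a stretch of 6 tested genes (highest 3), which argues against a chance arrangement. A regression of the stretch on the endothelial list over the 8 deletion mice left an intercept of -0.75 (-0.85 to -0.65), which argues against a fall that follows the size of the endothelial response. Loss of 1 copy of the stretch could not be told apart from other causes, since only 2 further probe sets there exceeded the filter, with a median of -0.13. They were the dim Ttc22, at 0.08, and a probe set shared by Acot11 and Fam151a, at -0.35. As Acot11 was already among the fallen genes, this median cannot decide. Other DNA inherited with the Cre gene, such as an insertion or a strain segment, may also underlie the fall and was not tested, and neither was an effect of FoxO on the region.

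The endothelial list was higher by 0.37 with deletion, and its members did so unequally: 6 of 35 differed from the list mean, Ptprb, Clec14a and Cdh5 above it by 0.36, 0.39 and 0.20, and Robo4, Sox18 and Tal1 at -0.40, -0.45 and -0.32. This argues against a larger share of endothelial RNA as the whole cause, although dim probe sets compress changes and Sox18 and Robo4 read 5.56 and 5.77 in the controls. A lower share of fibre RNA would raise other cell types alike. Of 7 other lists 2 shifted less, pericytes and smooth muscle by 0.24 (exact permutation p adjusted = 0.0011) and satellite cells by 0.43 (exact permutation p adjusted = 0.0060). The other 5, with macrophages and Schwann cells nominally above the endothelial list, were not shown to differ from it (exact permutation p adjusted from 0.665 to 0.755). The satellite cell list shares Myog, Chrng and Ncam1 with the denervation response list, and the pericyte list holds Abcc9, at 11.09 in the controls. How much of these 2 lists is read from fibres was not analysed, so the test cannot decide on a lower share of fibre RNA. With the liver list as a covariate the endothelial difference was 0.36 (0.18 to 0.53), which argues against carried-over liver transcripts as the whole cause. Without the mice high in Alb the endothelial difference was 0.24 (exact permutation p = 0.0429 before adjustment), so a part played by those mice stays open. More endothelial cells together with regulation of single genes may explain the pattern, as may Mx1-Cre activity outside the endothelium, which was not tested.

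Liver transcripts were high in controls 2 and 7 and deletion mice 1, 2, 4 and 5, with Alb at 11.17, 11.08, 11.68, 11.21, 11.61 and 10.02. The 20 genes moved together, with a median pairwise correlation across mice within groups of 0.912 against at most 0.153 in random lists, which is consistent with liver RNA carried into these samples, though plasma protein expression in muscle was not excluded. With 2 control mice above the deletion median of 5.76, the FoxO deletion cannot be the only cause.

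A chance split of the mice is argued against for the number of changed genes: 249 in the real grouping, and only that 1 of 100 splits reached it, with 2 genes as the highest other. The 100 were drawn from 6435 possible splits, mirror images counted once, so a rare split with as many genes was not excluded. Other splits mix both groups, and the real difference then widens their spread, which may lower their counts. Chance cannot be excluded for the number of lists called by camera: 11 in the real grouping, reached by 34 of 100 splits, with 18 as the highest other.

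Single mice stood apart from the rest of their group in 19 of 228 sets of values, where chance gives 11.4. Foxo1 was 8.23 in deletion mouse 4 and Plpp3 was 7.44 in deletion mouse 8. Flt4 was 5.54 in control 3, and Mmrn1 was 5.09 and Ldhb 7.73 in control 5. Control 1 had Pmp22 at 10.07, Mal at 8.24, Trim63 at 9.27 and the Schwann cell list at 6.95. Pfkp was 5.12 in deletion mouse 8, Pfkm was 11.52 in deletion mouse 5 and Suclg2 was 8.79 in deletion mouse 6. Isg15 was 5.88 in control 6, and control 7 had Gbp3 at 6.84, the interferon list at 6.57 and the antigen presentation list at 6.77. The slow fibre list was 6.48 in control 5, the vessel signalling list was 7.01 in control 4, and the antigen presentation list was 5.60 in deletion mouse 8. Of 6491 probe sets above the filter without a single gene symbol, 45 were higher with deletion and 10 lower (limma, adjusted over 20737 probe sets).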

How the results depend on the processing

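The alternatives with the liver list or without the mice high in Alb were added after the data were seen, and for the changes given here the cause was not tested unless stated. The 33 genes past the threshold that the naming rule chose and 19 named after their values were seen kept their direction wherever they were measured. The 249 changed genes (208 higher, 41 lower) became 137 (116, 21) with no filter, 68 (56, 12) with Welch's test, 452 (348, 104) with the leading residual component, 119 (99, 20) with the slow fibre covariate, 131 (111, 20) with the liver covariate and 505 (381, 124) at the looser threshold, which calls more by construction. Of these 120, 65, 249, 114, 131 and 249 were among the 249. The residual component was taken after the group means were removed. By construction it could not change a fold change, only the error and so the calls. Without the mice high in Alb 7 passed (4, 3), 6 of them among the 249, where fewer mice were compared. Centring gave 126 higher and 67 lower, and array weights gave 65 lower. Without 1 mouse the count ran from 107 (90, 17) without deletion mouse 6 to 680 (538, 142) without deletion mouse 8. With the replicate number as a block 213 genes passed, 155 of them shared, and same-numbered mice correlated from -0.083 to 0.250, so they were not treated as pairs. Lists called by camera numbered 11, against 18 after centring, 0 with an estimated correlation, 3 with fry, 3 with exact permutation, and 6 to 15 without 1 mouse. With the residual component Foxo3 passed, at a difference of 0.50 that this covariate could not change. Without 1 mouse Foxo1 ran from -0.052 to 0.12, Foxo3 from 0.38 to 0.56 and Foxo4 from -0.28 to -0.18. Genes that were not past the threshold turned direction: Pdk4 to -0.039 with centring, -0.025 with array weights, -0.078 with the slow fibre covariate and -0.033 with the liver covariate, and Rps24 to 0.029 with the mean of probe sets. Without the mice high in Alb Foxo1 turned to -0.12, Pcx to -0.014, Pdk4 to -0.086, Socs3 to 0.033 and Bcl2l11 to -0.023. Without 1 mouse Ldhb ran from -0.13 to 0.019, Lmod1 from -0.052 to 0.017, Mmrn1 from -0.11 to 0.057, Pdk4 from -0.074 to 0.070, Robo4 from -0.079 to 0.022 and Sox18 from -0.16 to 0.013. Signal near background limits the dim genes.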

Other observations

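The genes and the list described here were chosen after their values were seen, and so was the test of that list. Kera, Fmod and Chad, proteoglycans and matrix proteins of tendon or cartilage, fell by 1.19 (SE 0.24), 0.49 (SE 0.10) and 0.48 (SE 0.10), with limma adjusted p-values of 0.0189, 0.0175 and 0.0205. They prompted a list of 14 tendon genes, so only the 11 other genes test it. Over these, which include Tnmd at -0.43, Scx at -0.35 and Tnc at 0.56, the mean differed by -0.17 (-0.37 to 0.02, exact permutation p = 0.0779), and 0 of them passed with limma, so a shift of tendon genes as a group was not shown.

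Further genes rose in the deletion mice outside the lists. Plk2, a polo-like kinase, rose by 0.72 (SE 0.08), Adgrg6, an adhesion receptor, by 0.93 (SE 0.13), Trpm3, a cation channel, by 0.63 (SE 0.09) and Tll1, a metalloprotease, by 0.84 (SE 0.13), each with 8 of 8 deletion mice above every control. Igfbp7, a secreted protein that binds insulin-like growth factors, rose by 0.65 (SE 0.11), with 7 of 8 above every control.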
